A study of Mus musculus with 4 samples.

How the data were processed

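The series holds 4 droplet single-cell RNA libraries from cultures of mouse bone marrow-derived macrophages, which are macrophages grown from marrow precursors. Control mice and mice with a myeloid-specific deficiency of the ribosomal protein L13a, encoded by Rpl13a and called KO here, were each sampled at day 4 and day 12 of differentiation. Each of the 4 conditions has 1 library. The labels state that male and female mice were used in a 1:1 ratio. They name neither the Cre driver nor the part of the gene that was removed.

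The deposited values are raw UMI counts per gene and barcode, where a UMI is a molecular tag that lets copies of 1 molecule be counted once. Per the file headers the counts were made with Cell Ranger 6.1.2, and per the submitters' processing notes the genome build was mm10. The gene annotation and the rule by which barcodes were called cells are not given in the sources used here. The tables list 22050 genes. Of their gene identifiers, 21873 are present in GENCODE mouse release M21 for GRCm38, the same build, from which gene positions were taken, and 177 are not. Xist is not among the genes analysed here.

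The libraries held 13241 barcodes (control day 4), 13369 (KO day 4), 13761 (control day 12) and 13901 (KO day 12), and the smallest count in any barcode was 500 UMIs. Barcodes were kept with at least 500 genes and at most 15% mitochondrial UMIs. Doublets were scored with Scrublet in Scanpy 1.11.5 per library. Its automatic threshold, the setting chosen before the data were examined, marked 2.40% and 4.31% of filtered barcodes in the control and KO libraries at day 4 and 15.9% and 0.0081% at day 12, so it did not work in the last library. The alternative planned with it was used in its place: in every library the top-scoring barcodes were removed up to an expected rate of 0.8% per 1000 barcodes. This left 8688, 11351, 10279 and 10980 cells, with 167600703, 180810858, 116511386 and 123479856 UMIs.

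Counts of all kept cells of a library were summed and scaled to a total of 1000000 (CPM). A log2 fold is the log2 of the ratio of 2 CPM values, each with 1 CPM added. With 1 library per condition no difference between conditions was tested and none has a replicate check. A fit of genotype plus day over the 4 libraries, which would take the difference between the days as error, was not made. Intervals are exact 95% Poisson intervals of a level, exact conditional binomial intervals of a ratio and Clopper-Pearson intervals of a share of cells. They cover counting error only, not variation between mice or cultures. A count of 0 was read against a floor of 3 counts. Named genes follow a rule fixed before the data were examined. They reach 20 CPM in the higher library and exclude mitochondrial and sex-linked marker genes and unnamed gene models. The rule takes the 12 largest log2 folds each way between KO and control at each day, the 10 largest each way between days in each genotype, the 6 largest differences of the KO effect each way, and up to 4 members of each gene list per day. Some genes that the rule takes are not reported here. The 27 gene lists and 14 marker lists were fixed at the same time. A list median covers members at 5 CPM or more and is set beside the medians of 10000 random lists of the same size matched on mean level, as a description of these libraries.

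Cells of the 4 libraries were clustered together on 2000 variable genes without Rpl13a and sex-linked markers, with 30 principal components, 15 neighbours and Leiden clustering at a resolution of 0.6 (leidenalg 0.10.2). The rule for naming the 22 clusters was set after they were seen. A cluster took the class with most markers among its 10 genes of highest fold, if at least 1 of those genes was such a marker. The median log2 fold of all markers of the class also had to be 1 or more, with at least 3 at 20 CPM. Low-depth clusters stayed unnamed unless 5 or more of the 10 genes were markers. The largest clusters were mostly from 1 library each, and 1 of them was led by an osteoclast marker with no macrophage marker among its 10 leading genes. A macrophage-like class was therefore not compared between libraries, and these clusters are called the remaining clusters. They had 11 to 13 macrophage markers at 20 CPM or more, as did several named clusters, and 5 of them, mostly of day 4 cells, also had 8 or 9 monocyte markers at that level.

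The fold, interval and list functions were tested on simulated Poisson counts for each comparison, with 200 genes changed by known folds. In the simulation of KO against control at day 4, on 5858 genes, all 100 genes changed 2-fold and all 100 changed 4-fold passed 1.5-fold in the right direction, and 0 of 5644 unchanged genes did. The simulation holds no variation between cultures. Alternatives covered cell and doublet filters, median-of-ratios and edgeR 4.0.16 TMM scaling, equal weight per cell, the pseudocount, the CPM minimum, cells with Y-linked UMIs, cells without UMIs of Mki67 or Top2a, and the clustering settings. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and R 4.3.3.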

Results

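The data were UMI counts of single cells from bone marrow-derived macrophage cultures of control and L13a KO mice at day 4 and day 12, with 1 library per condition. Kept cells had a median of 19176 UMIs and 4421 genes in control day 4, 15458 and 3931 in KO day 4, 9919 and 3075 in control day 12, and 10721 and 3165 in KO day 12. After each cell was thinned to 3000 UMIs the median number of genes was 1471, 1452, 1440 and 1414 in the same order, with 593, 972, 766 and 465 shallower cells left out. Barcodes above 15% mitochondrial UMIs made up 24.8% of control day 4, 3.63% of KO day 4, 14.9% of control day 12 and 9.72% of KO day 12, so RNA quality before filtering differed between the genotypes. No difference below has a replicate check, and intervals cover counting error only.

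The first comparison checks the targeted gene. Rpl13a (ENSMUSG00000074129, GRCm38 chromosome 7, 45125558 to 45128761, minus strand), which encodes a protein of the large ribosomal subunit, was lower in both KO libraries, where it was still counted. Its level was 239 CPM in control and 157 CPM in KO at day 4 (ratio 0.658, 95% interval 0.648 to 0.668) and 164 and 100.4 CPM at day 12 (ratio 0.614, 0.5998 to 0.628). Among cells thinned to 3000 UMIs, 47.4% of control and 28.3% of KO cells had an Rpl13a UMI at day 4, and 36.1% and 22.6% at day 12. Without thinning these shares were 87.8% and 57.3% at day 4, and 70.4% and 48.1% at day 12. The median level of the other large-subunit protein genes was 1696 CPM in control day 4, far above that of Rpl13a. In cells without Mki67 or Top2a UMIs the log2 fold at day 4 was -1.71 in place of -0.60. That selection kept 1414 of 8688 control cells and 4275 of 11351 KO cells, so it compares unlike parts of the libraries. Free RNA in the droplets can add UMIs to cells without the messenger, and since no cell class lacks this gene that background was not measured. Reads shared with pseudogenes may be missing from or added to these counts, and a tag near the 3' end may lie outside the removed part, so the remaining signal does not measure intact messenger.

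**Figure D1:**
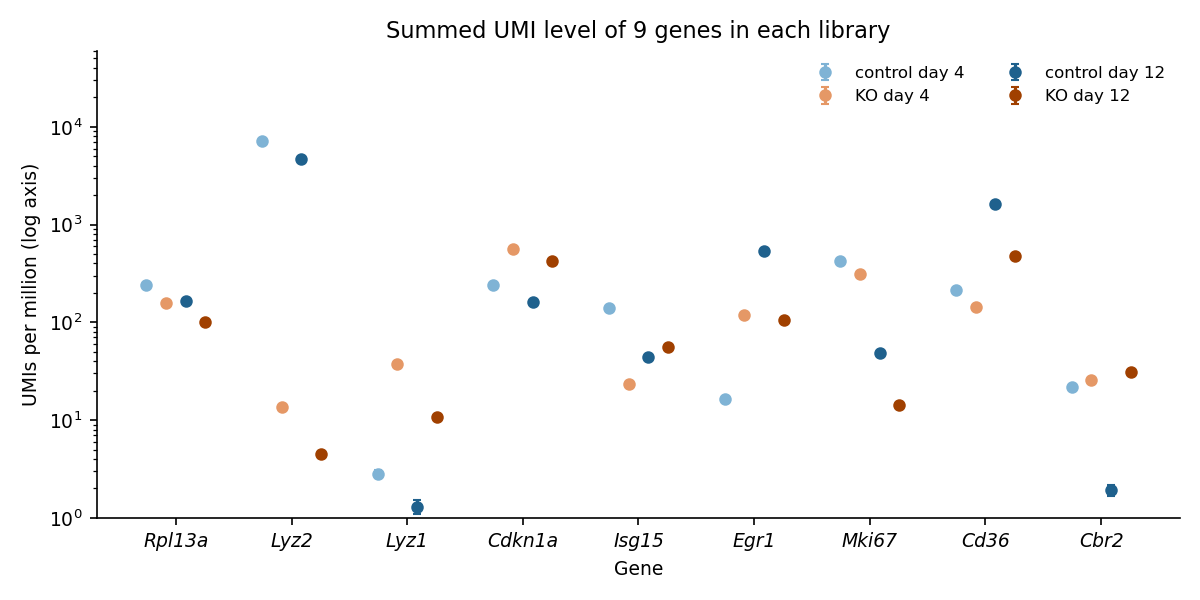
Summed level of 9 genes, in CPM on a log axis, in each of the 4 libraries. Points are the library's level and bars the exact 95% Poisson interval, mostly smaller than the point. Lyz2 lies at 7115 and 4642 CPM in the control libraries and at 13.6 and 4.45 CPM in the KO libraries, while Rpl13a lies between 100.4 and 239 CPM in all of them.

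KO was then compared with control at day 4, early in differentiation. The largest difference was in Lyz2, the lysozyme gene of macrophages and neutrophils, at 7115 CPM in control and 13.6 CPM in KO (ratio 0.00191, 0.00183 to 0.00199). Its paralog Lyz1 was higher in KO, at 37.3 against 2.83 CPM. The counting could split reads between these near-identical genes, so their separate levels are uncertain. The X-linked gene Mid1 was at 22.1 CPM in control and 0.332 in KO, and Erdr1, a multicopy gene of the pseudoautosomal region whose counts are uncertain, at 26.7 and 0.354 CPM. It is not known whether the near absence of Lyz2 and Mid1 follows from loss of L13a or from another difference between the mice. Differences between KO and control, here and below, therefore cannot be assigned to loss of L13a alone.

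Genes of the type I interferon response formed the most uniform group at day 4. All 21 measured members were at least 1.5-fold lower in KO, with a median log2 fold of -1.72 that lay below all of the 10000 matched random lists. Ifit3 was at 60.6 CPM in control and 8.06 in KO, the ubiquitin-like modifier Isg15 at 140.3 and 23.5 (ratio 0.168, 0.162 to 0.173), Rsad2, which encodes viperin, at 143 and 27.4, and Ifit2 at 52.2 and 8.88. The chemokine Cxcl10, an interferon target, was also lower (log2 fold -1.84), as was Ccl12 (-1.98). MHC class I presentation genes had a median of -0.32 and MHC class II genes of -0.36, but the latter was -1.05 in cells without UMIs of the cycling genes Mki67 and Top2a and 0.18 in the remaining clusters, so its direction depends on the cells taken.

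Target genes of p53, the transcription factor activated by DNA damage and by ribosome assembly defects, were higher in KO at day 4. Of 18 measured members 12 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 fold of 0.88. The highest were Trp53inp1 (7.10 CPM in control, 37.4 in KO), Zmat3 (9.95 and 45.8), Phlda3 (10.7 and 45.3) and Mdm2, the ubiquitin ligase of p53 (108 and 349, ratio 3.24). The cell cycle inhibitor Cdkn1a stood at 244 and 560 CPM.

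Immediate early genes, which cells switch on within minutes of a stimulus, were also higher in KO at day 4. Dusp1 was at 49.5 CPM in control and 436 in KO, Egr1 at 16.6 and 119.6, Fosb at 19.3 and 118, and Fos at 74.1 and 423. The whole list of immediate early and heat shock genes had a median of 0.44, with 7 of 17 members at least 1.5-fold higher. Genes of the NF-kB response went both ways, with 5 of 20 higher and 5 lower by that measure (median 0.33); the neutrophil-attracting chemokine Cxcl2 was at 89.1 and 353 CPM and the inhibitor gene Nfkbia at 209 and 129. Nfkbiz and Trib1 were among the 12 genes furthest above control (log2 folds 1.83 and 1.87). Myeloid transcription factors had a median of 0.50, with Klf2 at 1.66 and Klf4 at 1.10.

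Over all cells, replication and division genes were lower in KO at day 4 by a small amount. The S phase list had a median log2 fold of -0.40 and the mitosis list of -0.44, and 5 of 24 members of each were at least 1.5-fold lower, including Gins2 (-0.90) and Prc1 (-0.74). In cells without Mki67 or Top2a UMIs the medians were -0.98 and -0.87. That setting selects on members of the mitosis list and kept unlike parts of the libraries, 1414 control and 4275 KO cells. Within classes the direction was not shared by all. The S phase and mitosis medians were 0.18 and 0.17 in neutrophil-like cells and 0.11 and -0.045 in progenitor-like cells. They were -0.45 and -1.05 in dendritic cell-like cells, -0.49 and -0.45 in the remaining clusters and -0.51 and -0.41 in the low-depth clusters. Nucleolar genes had a median of -0.27, with Ddx21 at -0.62. Proteins of the large subunit other than Rpl13a had a median of 0.0011 and those of the small subunit of 0.058; in the large subunit Rpl22l1, a paralog of Rpl22, was at -0.76. Under different scalings and cell filters the large-subunit median ranged from -0.0695 to 0.0661, on both sides of 0.

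Of the classically activated (M1) genes measured at day 4, 5 of 11 were at least 1.5-fold higher and 3 lower (median 0.57, but 0.098 in cells without Mki67 or Top2a UMIs, -0.11 in progenitor-like and -0.31 in low-depth cells), and of the alternatively activated (M2) genes 3 of 10 were higher and 0 lower (median 0.052). Tnf was at 50.3 CPM in control and 32.8 in KO, and the mannose receptor gene Mrc1 at 278 and 207. The lysosome list had a median of 0.20, led by the prosaposin gene Psap (log2 fold 0.89), and the oxidative stress list of 0.12. Complement and phagocytic receptor genes (-0.14), chemokines (-0.088), lipid uptake and efflux (0.12), cholesterol biosynthesis (-0.19), matrix remodelling (0.29), hypoxia response (0.026), glycolysis (-0.13), nuclear-encoded oxidative phosphorylation (-0.023), mitochondrially encoded proteins (0.045) and the stress and unfolded protein response (-0.14) had medians between -0.19 and 0.29. Single members stood further apart, such as C1qa (-0.96), the growth factor gene Igf1 (-1.40) and the fatty acid binding protein gene Fabp5 (-1.06). Only 3 reported targets of the L13a-containing GAIT complex, which silences translation, were measured, with a median of 0.28; changes in translation were not measured here.

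By size of difference, 6152 genes reached 20 CPM in the higher library at day 4, of which 42 were at least 2-fold higher and 68 at least 2-fold lower in KO. Jchain, an antibody chain gene, had the largest positive fold (27.7 CPM in KO, 0.0418 in control), but 5 of 11351 cells held 50% of its UMIs.

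**Figure D2:**
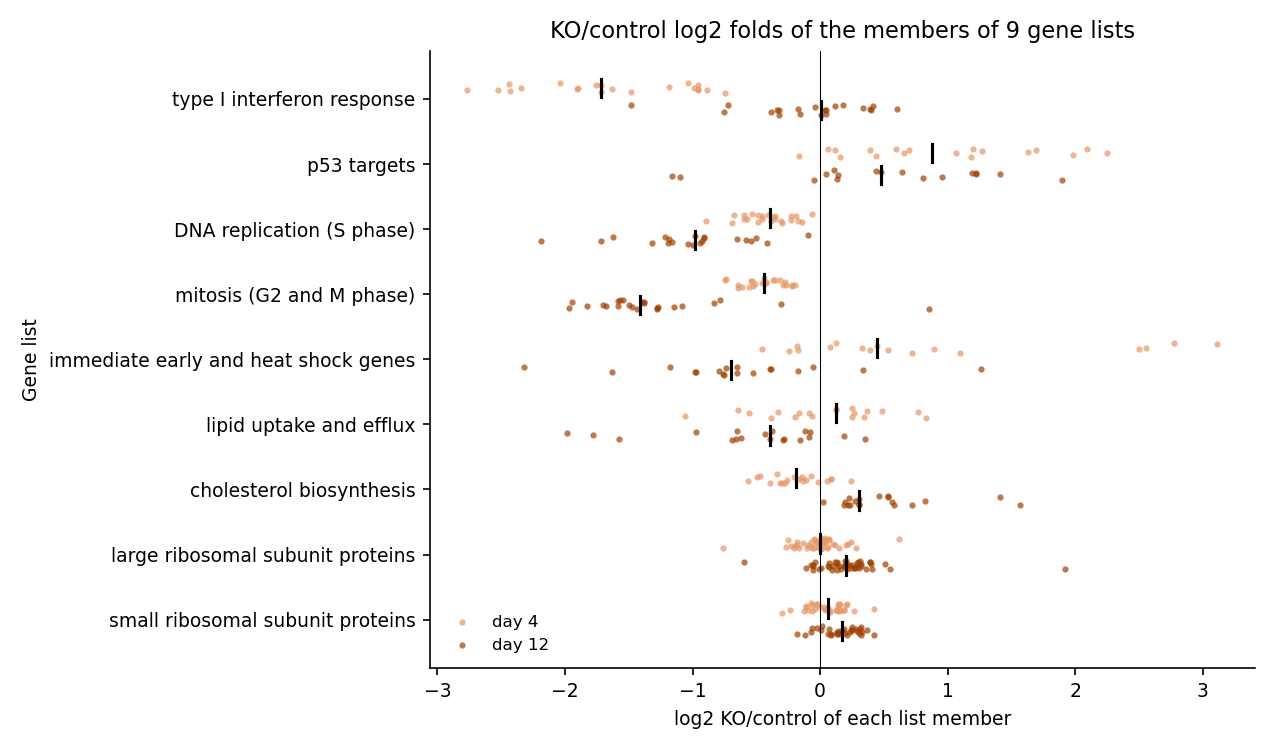
log2 KO/control of each measured member of 9 gene lists, with day 4 in light orange and day 12 in dark brown; each point is a gene and the black bars are list medians. The interferon median is -1.72 at day 4 and 0.0031 at day 12, and the mitosis median is -0.44 at day 4 and -1.41 at day 12.

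The same comparison at day 12 asks how the KO cells differ once differentiation is advanced. Taken over all cells, replication and division genes were lower in KO by more than at day 4. Of 24 mitosis genes 22 were at least 1.5-fold lower (median log2 fold -1.41), with Top2a at 68.4 CPM in control and 18.6 in KO and Mki67 at 48.2 and 14.3. Of 21 S phase genes 16 were lower by that measure (median -0.98), such as Mcm5 at 35.5 and 10.9 CPM and the replication clamp gene Pcna at 281 and 125. In cells without UMIs of Mki67 or Top2a the mitosis median was -0.25 and the S phase median -0.60. At day 4 they were -0.87 and -0.98, so the order of the days turned there. That setting selects on members of the mitosis list.

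Target genes of p53 were again higher at day 12, with 8 of 17 at least 1.5-fold higher, 2 lower and a median of 0.48. Phlda3 was at 8.18 CPM in control and 33.2 in KO, Cdkn1a at 160.6 and 428, Trp53inp1 at 23.9 and 57.2, and Mdm2 at 99.8 and 107. Lyz2 was at 4642 and 4.45 CPM and Mid1 at 27.9 and 0.17, as near to absent as at day 4, and Lyz1 was at 1.296 and 10.7 CPM.

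Lipid-handling genes of macrophages were lower in KO at day 12. The uptake and efflux list had a median of -0.40, below all matched random lists, with 8 of 19 members at least 1.5-fold lower and 0 higher. Nr1h3, which encodes the sterol sensor LXR alpha, was at 39.5 CPM in control and 9.25 in KO, the scavenger receptor gene Cd36 at 1637 and 476, Fabp4 at 162 and 53.6, and the lipoprotein lipase gene Lpl at 5761 and 2936. Cholesterol biosynthesis genes were higher (median 0.31), with 4 of 19 at least 1.5-fold higher and 0 lower, among them Fdps (log2 fold 1.41).

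Genes furthest above control at day 12 included Cbr2, a carbonyl reductase gene (1.91 CPM in control, 31.1 in KO), the leukotriene C4 synthase gene Ltc4s (15.6 and 76.1), the lectin receptor gene Cd33 (22.0 and 92.7), Ednrb (13.9 and 50.7), Fcrls (103 and 334), Clec4e (9.51 and 33.6) and the ribonuclease genes Ang (4.35 and 20.3) and Rnase4 (27.5 and 89.7), which share a locus. Fcgr2b, the inhibitory Fc receptor gene, had a log2 fold of 1.25 and Axl, a receptor for dying cells, of -1.30. Immediate early genes went the other way from day 4, with a list median of -0.70 and 11 of 18 members at least 1.5-fold lower; Egr1 was at 531 CPM in control and 105 in KO and Dusp1 at 818 and 264.

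Among polarization genes at day 12, 2 of 6 M1 genes were at least 1.5-fold higher and 2 lower (median -0.15, and from -0.43 to 0.43 under alternatives), with Cd86 at 1.39 and Tnf at -1.11. Of 10 M2 genes 3 were higher and 5 lower (median -0.65), with Clec10a at 1.09, Mrc1 at 437 CPM in control and 800 in KO, and Egr2 at -1.54. Several genes furthest below control came from few cells of other types: Fn1 (37.4 and 0.211 CPM), Col1a2, Cald1 and Acta2 from 28 stromal cell or fibroblast-like cells found in control alone, and Ngp and S100a9 from 23 neutrophil-like cells. Those classes held 91.1% of the UMIs of Cald1 in control day 12, 95.9% of those of Fn1, which is also on the M2 and matrix lists, and 95.1% of those of Ngp and S100a9. In the remaining clusters the log2 fold of Fn1 was -0.91 in place of -4.99, that of Col1a2 -0.47 in place of -4.52, that of Cald1 -0.83 in place of -4.30, that of Acta2 -0.50 in place of -4.09, that of Ngp -1.28 in place of -4.68 and that of S100a9 -2.97 in place of -4.11.

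The interferon list did not differ as a whole at day 12 (median 0.0031, 1 of 21 members at least 1.5-fold higher and 3 lower). MHC class I genes had a median of 0.32 and MHC class II genes of -0.39, with H2-Aa at -0.74. Large-subunit proteins had a median of 0.20 and small-subunit proteins of 0.17, and nucleolar genes of -0.15. Other medians were 0.27 for complement and phagocytic receptors, 0.13 for the NF-kB response, -0.18 for chemokines, -0.074 for the lysosome, -0.38 for matrix remodelling, -0.15 for myeloid transcription factors, -0.27 for the stress and unfolded protein response, -0.14 for oxidative stress, -0.034 for hypoxia, -0.12 for glycolysis, 0.086 and -0.082 for nuclear and mitochondrial respiratory genes, and -0.066 for 5 GAIT targets. Between KO and control the macrophage marker median was 0.061 at day 4 and 0.22 at day 12, that of monocytes 0.19 and -1.49, and that of neutrophils 0.25 and -3.24; progenitor markers had 0.090 at day 4 and osteoclast markers -0.10 at day 12. With 3 measured members each, erythroid markers had a median of 0.15 at day 4, and endothelial and stromal markers had 0.42 and -4.04 at day 12. At day 12 neutrophil-like cells numbered 23 in control and 3 in KO, and stromal cell or fibroblast-like cells 28 and 0. The neutrophil and stromal medians at day 12 can thus rest on few cells. The other marker lists had 2 measured members or fewer. At 20 CPM or more there were 5875 genes, of which 45 were at least 2-fold higher and 63 at least 2-fold lower in KO. With TMM scaling these counts were 56 and 56, so their balance depends on the scaling.

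**Figure D3:**
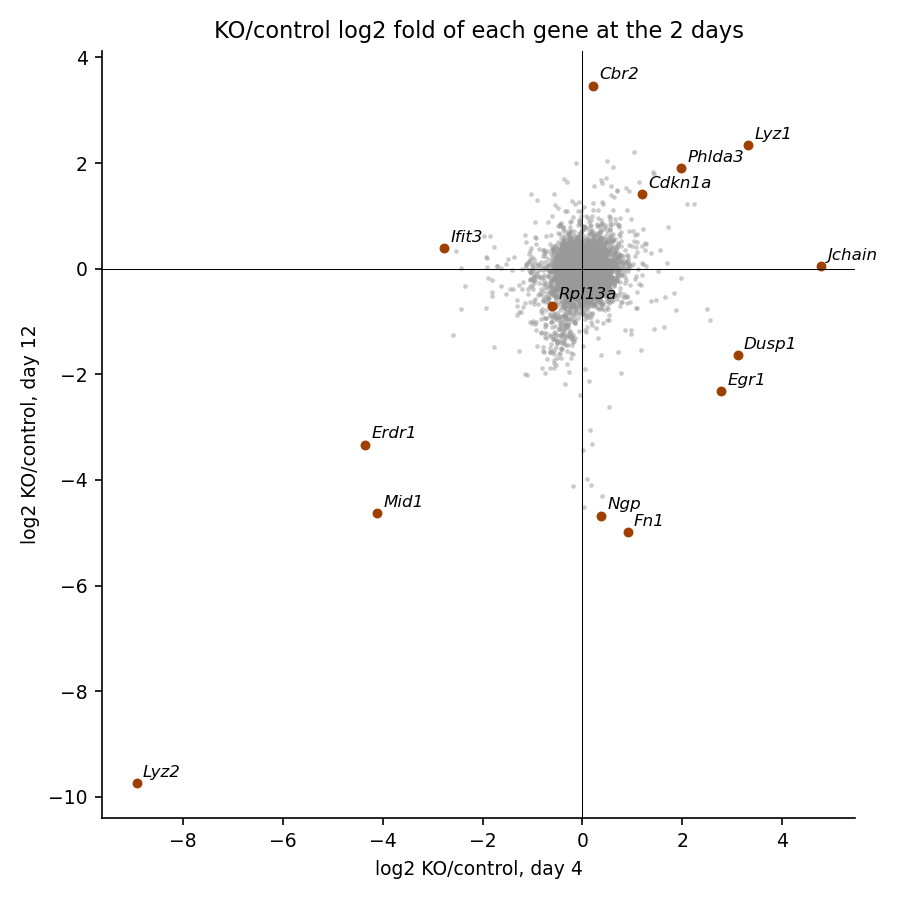
log2 KO/control of each gene at 20 CPM or more in any library, at day 4 on the x axis and day 12 on the y axis, with 14 genes named. Lyz2, Mid1 and Erdr1 lie far below 0 at both days, Egr1 and Dusp1 lie above 0 at day 4 and below 0 at day 12, and Pearson's r across the 6697 genes was 0.21.

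The KO/control folds of the 2 days were set against each other without a test. Most genes lay within 1.5-fold at each day, which limits any correlation. At least 1.5-fold higher or lower were 237 and 255 genes at day 4, and 177 and 413 at day 12. Across 6697 genes at 20 CPM or more in any library, which are not independent replicates, Pearson's r of the log2 folds at the 2 days was 0.21 (Spearman's rho 0.043), and 0.15 without Lyz2. At least 1.5-fold lower at both days were 79 genes, against 15.7 for independent lists of those sizes, and at least 1.5-fold higher at both were 35, against 6.26. Counts in opposite directions were also above that level, with 25 genes higher at day 4 and lower at day 12, against 14.6, and 12 lower and then higher, against 6.74. The largest gains from day 4 to day 12 in log2 fold were those of Cbr2 (3.25), Ifit3 (3.16) and Isg15 (2.86). The largest losses, at days that also differed in Y-linked transcripts, were those of Fn1 (-5.90), Egr1 (-5.10), Ngp (-5.05) and Dusp1 (-4.74). Those of Fn1 and Ngp rest on few cells. In the remaining clusters the folds at day 4 and day 12 were 1.00 and -0.91 for Fn1, and 1.21 and -1.28 for Ngp.

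Day 12 was compared with day 4 in each genotype to follow differentiation. Macrophage markers were higher at day 12 in both genotypes, with list medians of 1.73 in control and 1.96 in KO, and markers of monocytes (-4.72 and -6.05), granulocyte-monocyte progenitors (-4.61 and -5.76) and neutrophils (-4.12 and -6.57) were lower. Osteoclast markers had medians of 1.47 and 1.29. The phospholipid transfer protein gene Pltp was at 8.84 CPM at day 4 and 1122 at day 12 in control, and at 10.04 and 1552 in KO, and Cd5l, a gene of tissue macrophages, at 7.88 and 689 in control and 18.2 and 682 in KO. The neutrophil protease gene Prtn3 was at 328 and 3.35 CPM in control and 343 and 0.17 in KO, and the monocyte gene Ly6c2 at 436 and 6.03 in control and 479 and 0.615 in KO. Elane was at 185 CPM in KO day 4 and had 0 UMIs in KO day 12, where 3 counts would be 0.0243 CPM.

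In both genotypes the lists for lipid uptake and efflux (2.01 in control, 1.72 in KO) and the lysosome (1.24 and 0.92) were higher at day 12, and mitosis (-2.63 and -3.67), S phase (-1.97 and -2.56), cholesterol biosynthesis (-2.09 and -1.45), nucleolar genes (-1.58 and -1.51) and glycolysis (-1.27 and -1.39) were lower. The interferon list was lower at day 12 in control (-0.70) and higher in KO (0.69). Immediate early genes had a median of 1.44 in control and -0.082 in KO. Median-of-ratios scaling moved the median gene of this comparison in KO from -0.12 to -0.0022, so small folds between days depend on the scaling.

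The days also differed in Y-linked transcripts. Among cells with 5000 or more UMIs, 89.6% of control and 88.9% of KO cells had a Y-linked UMI at day 4, and 0.059% and 0.030% at day 12. Differences between days therefore go along with a difference in the sex of the cells, while KO and control were alike in this respect at each day.

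Shares of cell classes were compared because the title of the series names diversity. Dendritic cell-like cells made up 5.64% of control (95% interval 5.16 to 6.15) and 4.64% of KO cells (4.26 to 5.05) at day 4. Their difference there was -0.997 percentage points and became -2.78 under the stricter cell filter. At day 12 their shares were 0.710% and 0.364%. Neutrophil-like cells made up 6.98% and 9.14% at day 4 and 0.224% and 0.0273% at day 12, but the difference at day 4 turned to -0.44 percentage points under the stricter cell filter. Granulocyte-monocyte progenitor-like cells made up 12.1% and 6.46% at day 4, and the sign of that difference depended on the clustering: it was 24.6 percentage points at a resolution of 0.3 and 1.23 with scores centred per library, so no direction is given. The remaining clusters held 70.3% and 75.7% of cells at day 4 and 91.4% and 96.3% at day 12. At day 4 that order turned in 4 other clusterings. Such shares were 78.1% and 54.6% at a resolution of 0.3, and 71.0% and 56.0% at 1.0, so no direction is given. A monocyte-like class, absent in the main setting, held 0.437% of control and 21.5% of KO cells at a resolution of 1.0. It held 3.48% and 19.1% with 15 components, and 16.1% and 22.0% with scores centred per library. The size of that difference thus depends on the clustering. Under the stricter filter a macrophage-like class held 29.3% of control and 1.19% of KO cells at day 12. That split depends on the naming rule and is not read as fewer macrophages in KO. In the main setting no cluster took that name. Clusters mostly of KO day 12 cells had macrophage marker medians of 1.045 and 0.963. A cluster mostly of control day 12 cells had 0.997, and the cutoff was 1. The cluster at 1.045 passed that cutoff but had 0 macrophage markers among its 10 leading genes, where the rule needs at least 1. Each had 13 of those markers at 20 CPM or more. Unnamed low-depth clusters held 5.0%, 4.03%, 7.35% and 3.29% in the order control and KO at day 4, then at day 12. Stromal cell or fibroblast-like cells were 28 of 10279 in control day 12 and 0 of 10980 in KO day 12, which allows a share of up to 0.0273%.

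**Figure D4:**
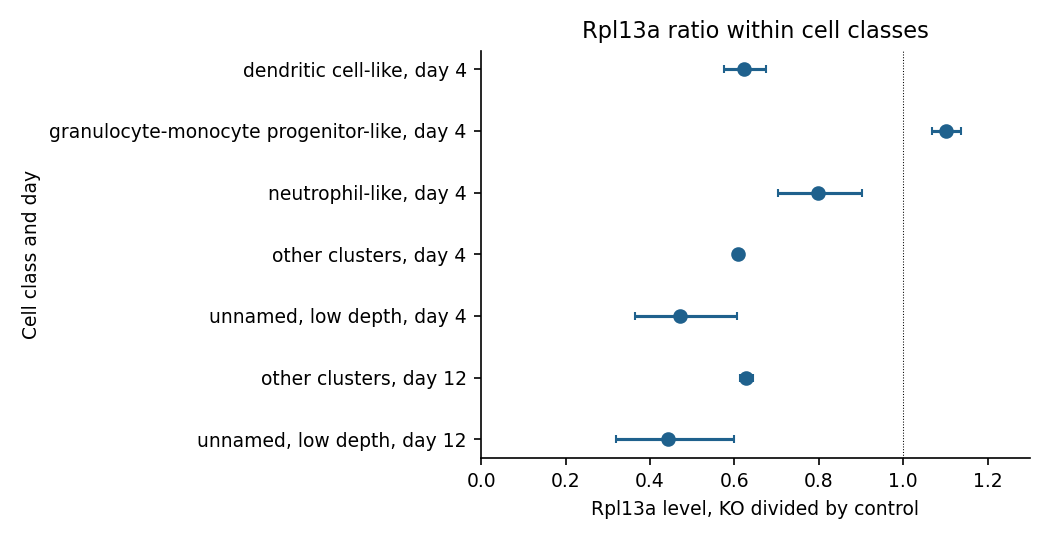
Level of Rpl13a in KO divided by control within each cell class that had 100 or more cells in both libraries of a day. Points are ratios and bars exact 95% intervals for counting error, and the dotted line marks equal levels. The ratio is 1.10 in granulocyte-monocyte progenitor-like cells at day 4 and 0.609 and 0.629 in the remaining clusters at day 4 and day 12, labelled other clusters.

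Within classes at day 4, Rpl13a had a KO/control ratio of 1.10 (1.07 to 1.14) in granulocyte-monocyte progenitor-like cells, 0.798 (0.704 to 0.904) in neutrophil-like, 0.623 (0.575 to 0.675) in dendritic cell-like and 0.609 (0.598 to 0.620) in the remaining clusters. The interferon list was lower in KO in each of the 5 classes, with medians from -1.81 to -1.06. The p53 list had medians of 1.08 in the remaining clusters, 1.08 in dendritic cell-like, 0.57 in progenitor-like, 0.32 in low-depth and 0.21 in neutrophil-like cells. Of the 27 lists, 19 had a median of the other sign in at least 1 of the 5 classes at day 4. Those with 1 sign in all 5 classes were interferon, p53, immediate early, NF-kB, lysosome, myeloid transcription factor, oxidative stress and GAIT genes.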

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

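The tests of explanations in this part were chosen only after the result was seen. Genes reported here were singled out because KO was at least 1.5-fold above control at one day and at least 1.5-fold below it at the other. These differences between days were not tested, since each condition has 1 library. The log2 folds at day 4 and day 12 were 3.11 and -1.63 for Dusp1, 2.78 and -2.32 for Egr1, 2.55 and -0.98 for Fosb, 2.497 and -0.77 for Fos, 1.87 and -0.78 for Trib1, and 1.47 and -0.59 for Ppp1r15a. They were 0.91 and -4.99 for Fn1, 0.61 and -0.59 for Sod1, -0.73 and 0.61 for C1qb, and -0.96 and 0.60 for Bst2. For Fn1, stromal cell or fibroblast-like cells held 95.9% of the UMIs in control day 12. Its fold at day 12 was -0.91 in the remaining clusters.

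The immediate early genes, higher in KO at day 4 and lower at day 12, are the clearest such group. At day 4 a different mix of the named classes is argued against, since within each of them at least 89.9% of the list's all-cell median was left. The remaining clusters, with 70.3% of control and 75.7% of KO cells at day 4, had a list median of 0.36. They differ in makeup between the libraries, so a different mix inside them is not decided. At day 12 a different mix cannot be told apart from a change within cells, since no named class could be compared; the low-depth clusters kept 71.4% of the median, and the remaining clusters hold nearly all cells and differ in makeup between the libraries. Handling that differed between the libraries may explain the pattern, because these genes respond within minutes to dissociation of cells. The list was higher in all 5 classes at day 4, which a handling difference and an effect of the genotype both predict, so with 1 library per condition they cannot be told apart.

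Y-linked transcripts, left out of the named genes and the gene lists, were present in 89.6% of deep cells in control day 4 and 88.9% in KO day 4. The shares without any Y-linked UMI, 10.4% and 11.1%, lay close to the 9.0% and 9.50% that Poisson counting gives if every cell carries them at the library's mean rate. At day 12 the shares with such UMIs were 0.059% and 0.030%. The labels state equal numbers of male and female mice.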

How the results depend on the processing

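No paired analysis was made, since each condition has 1 library. The planned cell selections not run were cells with Xist UMIs, since Xist is not among the genes analysed here, and macrophage-like cells, since that class was not compared; cells with Y-linked UMIs could be used at day 4 alone. Cells with 5000 or more UMIs and the remaining clusters were added after seeing the data, and the automatic doublet threshold, first planned as the main setting, is an alternative here. For 141 folds of named genes between KO and control of at least 1.5-fold, 1612 of 1615 values under alternatives kept their direction, and for 40 folds between days all 280 did; a gene can count under more than 1 comparison. The direction of Slc7a11 at day 4 turned in cells without Mki67 or Top2a UMIs (-0.28), and Mki67 and Top2a are at 0 there by construction. The interferon median at day 4 ranged from -1.81 to -1.43 and the p53 median from 0.61 to 1.08 at day 4 and from 0.46 to 0.55 at day 12. Medians on both sides of 0 were those of MHC class II (-1.05 to 0.18), M2 genes (-0.030 to 0.11), chemokines (-0.20 to 0.10), hypoxia (-0.046 to 0.036), large-subunit proteins, mitochondrially encoded proteins (-0.29 to 0.096) and nuclear respiratory genes (-0.058 to 0.030) at day 4. At day 12 they were those of M1 genes, chemokines (-0.33 to 0.075), hypoxia (-0.074 to 0.032), GAIT targets (-0.11 to 0.0021) and interferon genes (-0.060 to 0.071).

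The log2 fold of Rpl13a at day 4 became -0.78 with equal weight per cell, -1.71 in cells without Mki67 or Top2a UMIs and -0.71 in the remaining clusters; at day 12 it became -0.65 with median-of-ratios scaling, -0.63 with TMM and -0.66 in the remaining clusters. In cells without Mki67 or Top2a UMIs the S phase median was -0.98 at day 4 and -0.60 at day 12. The mitosis median was -0.87 and -0.25 there. At day 4 that setting kept 1414 of 8688 control cells and 4275 of 11351 KO cells, which are unlike parts of the libraries. With equal weight per cell the mitosis median was -0.58 at day 4 and -1.19 at day 12, and with a pseudocount of 5 CPM it was -1.004 at day 12. Genes at least 2-fold higher at day 4 numbered 73 with a 5 CPM minimum. Genes at least 2-fold lower numbered 103 at day 4 and 187 at day 12 with that minimum, which admits more genes, and 130 and 41 in cells without Mki67 or Top2a UMIs. KO minus control in neutrophil-like share at day 4 turned to -0.44 percentage points under the stricter filter. For progenitor-like share it turned to 24.6 at a resolution of 0.3 and 1.23 with centred scores, and was -4.38 without cell cycle genes, -2.52 with doublets kept, -0.86 under the stricter filter and -1.99 with 15 components. For dendritic cell-like share at day 4 it was -2.38 at a resolution of 0.3, -2.41 with doublets kept and -2.78 under the stricter filter. Except for the lower CPM minimum, the cause was not tested. A larger pseudocount shrinks the folds of genes at low levels, such as Mid1 at day 4 (-2.35 with 5 CPM). Mid1 had 3705 UMIs in control and 60 in KO there.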

Other observations

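The genes in this paragraph were chosen after their values were seen. They belong to no list fixed in advance, so nothing is said of their families. The linker histone genes Hist1h1b and Hist1h1e were at 620.2 and 142 CPM in control and at 182 and 44.8 CPM in KO at day 4, and Hist1h1c at 53.4 and 38.9. At day 12 Hist1h1b was at 39.2 CPM in control and 13.4 in KO, Hist1h1e at 17.3 and 17.4 and Hist1h1c at 91.1 and 163. Among interferon-induced transmembrane genes at day 12, Ifitm3 was at 901 CPM in control and 1930 in KO, Ifitm2 at 758 and 1522 and Ifitm1 at 15.1 and 22.3. Of the Fc receptor genes at day 12, Fcgr2b was at 79.3 and 190 CPM, Fcgr3 at 301 and 557, Fcgr1 at 161 and 148 and Fcgr4 at 55.0 and 31.9. The monocyte chemokine receptor gene Ccr2 was at 323 CPM in control and 583 in KO at day 4 and at 40.2 and 17.4 at day 12.

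Of the tests below, the one on the region around Rpl13a was set before its result was seen and the others after. Lyz2 was nearly absent from both KO libraries. The highest KO/control ratio in any class with 100 or more cells was 0.00545, in neutrophil-like cells, so the loss covered every class examined, progenitor-like cells included. Reads moved to the paralog Lyz1 are argued against, since Lyz1 and Lyz2 together were at most 0.00715 of the control level. Fewer mature macrophages are argued against too, since the lower of the macrophage marker medians at the 2 days was 0.061. A candidate explanation is a change at the Lyz2 allele itself, as when a Cre recombinase gene is placed in Lyz2 to drive myeloid deletion; the labels name no driver, and a variant of the mouse strain stays open.

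The interferon list was lower in KO at day 4. Poor-quality cells in the control library are argued against, because the median was -1.73 in cells with 5000 or more UMIs that pass the stricter filter. A different mix of cell classes is argued against, because the class median nearest to 0 was -1.06. A different mix of cells inside the remaining clusters, which differ in makeup between the libraries, is not covered. Cultures that differed for another reason, such as stronger interferon exposure of the control culture, cannot be told apart from the genotype, since the list was lower in all 5 classes and there is 1 library per condition. The absence of a difference in this list at day 12 (median 0.0031) leaves both open.

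Rpl13a was only partly lower in the KO libraries. One hypothesis is that deletion sets in after the progenitor stage, with free RNA as an unmeasured source of part of the remaining UMIs. At day 4 Lyz2, the candidate site of the driver, was at 5775 CPM in control progenitor-like cells and 7572 in the remaining clusters of control. If the driver sits there, its site was already active in progenitor-like cells, which the hypothesis has to allow for. The KO/control ratio of Rpl13a at day 4 was 1.10 in progenitor-like cells and 0.609 in the remaining clusters. That is what the hypothesis predicts for day 4, though these counts do not measure intact messenger. At day 12 0 of 10980 KO cells were progenitor-like in the main setting, yet the ratio in the remaining clusters was 0.629. Progenitor-like cells thus do not account for the Rpl13a still counted at day 12, which the hypothesis alone leaves unexplained. Under the other clustering settings the ratio in progenitor-like cells ranged from 1.01 to 1.13, except at a resolution of 0.3. There it was 0.711 in a class of 3315 KO and 398 control cells that were unlike each other, with Elane at 139 and 1472 CPM. Elane also differed in other settings, less strongly. It was at 311 CPM in KO and 724 in control with centred scores, 398 and 709 under the stricter filter, and 1952 and 1362 at a resolution of 1.0. The progenitor-like cells compared were thus not matched in stage. If p53 target levels followed the counted Rpl13a messenger class by class, their median would be near 0 in progenitor-like cells. It was 0.57, which argues against that simple form, although the class may hold cells at several stages. The single target Cdkn1a had KO/control ratios of 1.21 in progenitor-like, 1.86 in neutrophil-like, 2.09 in dendritic cell-like cells and 2.40 in the remaining clusters. That is the reverse order of the Rpl13a ratios in those classes. In the low-depth clusters its ratio was 2.33, at an Rpl13a ratio of 0.472, the lowest of the classes. The counts do not measure intact messenger, so whether p53 targets follow its loss cannot be decided.

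A flanking stretch of chromosome 7 carried along with the targeted allele might explain genes that differ the same way at both days. Of 6695 genes with a position, 114 did so by at least 1.5-fold, Rpl13a itself among them, and of its 58 neighbours within 10 Mb 0 did, which lay at percentile 19.9 of windows of the same width. Apart from Rpl13a, those genes thus lie outside that window, which argues against a stretch within it as their source. A longer stretch is not covered. A count of 0 among 58 is not unusual, since 1.70% of all 6695 genes differed that way. Genes that differ at 1 day are not covered: Cd33 (chromosome 7, 43524216 to 43544428), near Rpl13a, was at 22.0 CPM in control and 92.7 in KO at day 12 and at 32.9 and 46.7 at day 4, and a flanking variant stays open for it. Windows around Lyz2 and Mid1, chosen after their folds were seen, held 2 of 46 genes (Bbs10 and Lyz1, percentile 94.0) and 1 of 18 (Tlr7, percentile 95.7).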
